A study of Caenorhabditis elegans with 2 samples.

How the data were processed

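ChIP-seq had been performed on whole L1 larvae of Caenorhabditis elegans strain OP593, which expresses CEH-88 with TY1, EGFP and 3xFLAG tags from a transgene, with an antibody against GFP. Per the labels, chromatin was sonicated to a size range of 200 to 800 bp and the 2 libraries are biological replicates of 1 group, numbered 1 and 2 there. No sample of another strain, stage or antibody was analysed here. The labels point to a control experiment, whose data were not used here.

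The analysis started from peak lists that the authors deposited on assembly ce11, per the labels. For each replicate there was an IDR ranked list, which also holds regions below the threshold, and an IDR thresholded list. A further 2 such pairs cover the whole series, and the thresholded list of 1 pair is called conservative. The other carries no such name and was taken here as a pooled list, which the sources do not state. The aligner, the peak caller and their versions are not given in the sources used here. The deposited score of each region runs up to 1000 and follows the IDR on a log scale, on which 830 equals an IDR of 0.01. No peak in any of the 4 thresholded lists scored below 830. The deposited signal value is the caller's own measure of peak strength. It has no stated scale between lists. It was used to describe and rank peaks, to compare promoter peaks with other peaks of the same list, and to compare values and ranks between the replicates. The deposited lists also hold the −log10 of a q value, which entered no test, and a column with a constant placeholder. Of the ranked lists for the whole series, the one built from the replicates was recognised because the coordinates of its inputs match the replicates' own regions (68.4% and 78.5% against 0 in the other list). Its remaining inputs match no region of the replicates' own ranked lists exactly, so those lists may lack some called regions. This whole-series ranked list was paired with the conservative list. The 8 columns of per-replicate signal and summit in the ranked lists for the whole series were not used. Read depth was not given, so no interval here covers sampling of reads, and exact intervals (Clopper-Pearson, 95%) cover the counting of peaks or genes. Widths were mostly fixed, with a median of 350 bp in replicate 1, 360 bp in replicate 2 and 396 bp in the conservative list.

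Genes came from Ensembl release 115 (WBcel235, the same assembly as ce11) and sequence from the RefSeq copy of that assembly. All peaks ended within the lengths of its 6 nuclear chromosomes. A promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start, and a gene was a target, or bound, when a summit lay in its window. The conservative list was the main list. Replicate peaks were shared when they touched by at least 1 bp, tested against 10000 one-sided shuffles within chromosomes. A shuffle drew new positions at random along the whole chromosome, and the p from such random draws is called permutation p in the text. A replicate's signal at a peak was the strongest of the regions in its own ranked list that overlapped the peak. Promoter share and distance to noncoding genes (250 bp) were tested with 10000 one-sided shuffles of summits within chromosomes, chromosome counts with exact binomial tests, gene lists and differences between shares with Fisher's exact test, and signal at promoters with a permutation test of 100000 resamples. Hexamers, with reverse complements merged, were counted as present or absent in windows of 50 bp on each side of the summit and in windows 250 bp away on both sides, and each was tested with an exact binomial test of its summit windows among all windows that hold it. Families of tests were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold.

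The 30 gene lists, the 12 fixed hexamers, the tests, the alternatives called planned and the rule for named genes were chosen before the data were examined. The rule named the protein-coding gene with the nearest start to each of the 25 strongest conservative peaks, the 4 targets of highest signal in each list past the threshold and 2 in each other list, ceh-88 and unc-119, all homeobox targets up to 12, and the gene nearest the 3 strongest peaks of each replicate alone. Sequences, X-linked patterns and small RNA genes named outside this rule were chosen after their values were seen. Because the only samples are 2 replicates of 1 group, p-values describe peaks, genes or windows, not the spread between animals.

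The tests were tried on simulated data first. Of 10 gene lists with raised odds 8 were called, and of 20 unchanged lists 0. Of 20 planted hexamers 19 were recovered, and 0 hexamers were called with none planted. The windows of that simulation lay away from the summits. It therefore did not cover calls that come from the difference in G and C content between real summits and their flanks. Copied regions gave an overlap of 54% where 53.7% had been copied.

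The alternatives chosen in advance were the other list of the whole series, each replicate's own list, a score of at least 830, other promoter windows (500 and 2000 bp), midpoints, other backgrounds, other distances and window sizes. A score of 1000, the strongest summit within 500 bp, ranked regions as a null for overlap, a background matched on G and C content and peaks without tRNA genes were added after seeing the data. Repeated sequence was measured as the share of 30-mers in a summit window with another exact copy on the 6 chromosomes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.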

Results

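CEH-88 is a homeodomain protein of the nematode Caenorhabditis elegans. Its binding across the genome was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole first-stage (L1) larvae of age 6 h that had been synchronised by bleaching and starved. The worms carried a transgene in which ceh-88 is fused to TY1, EGFP and 3xFLAG tags, together with an intact unc-119 gene, and the fusion protein was recovered with an antibody against GFP. There was 1 group of 2 biological replicates, so the comparisons that the design allows are replicate 1 against replicate 2, and bound regions against the rest of the genome or against regions that the same caller ranked too low to pass. Read depth was not given in the sources used here, and the depth behind each peak is therefore unknown. Coordinates are those of assembly ce11.

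The 2 replicates gave peaks at many of the same places, and replicate 1 gave more of them. Replicate 1 had 1128 peaks past the authors' threshold on the irreproducible discovery rate (IDR) and replicate 2 had 698, a ratio of 1.62. The list built from both replicates, called conservative by the authors, held 1171 peaks, and the other list of the whole series, taken here as a pooled list, held 1349, a ratio of 1.15. Of the replicate 1 peaks, 546 (48.4%, exact 95% interval 45.5 to 51.4) touched a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 548 (78.5%, interval 75.3 to 81.5) touched a replicate 1 peak. Regions placed at random within chromosomes touched the other list in 0.469% and 0.754% of cases on average, with permutation p = 1e-04 in both directions, the smallest that 10000 one-sided shuffles can give. Drawing regions from the same replicate's own ranked list instead raised these averages to 0.929% and 1.29% (permutation p = 1e-04 in both directions).

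The signal value of the conservative peaks was correlated between the replicates. Of the 1171 peaks, 1152 had a region in both replicates' ranked lists, and across them Pearson's r of the log2 signal was 0.82 and Spearman's rho was 0.721. The log2 ratio of the replicates' signals had an SD of 0.50 over these peaks. Neighbouring peaks can take their values from the same replicate region. The overlapping peaks with signals of 465 and 171 at X 2996931 and X 2997145 both had 234.1 and 224.4. Some pairs may therefore be those of a stronger neighbour. Peaks are not independent replicates, and the IDR step selects regions of similar rank in both replicates. Across the 65431 ranked regions with a signal in both replicates, most of them below the threshold, r was 0.31 and rho was 0.211.

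**Figure D1:**
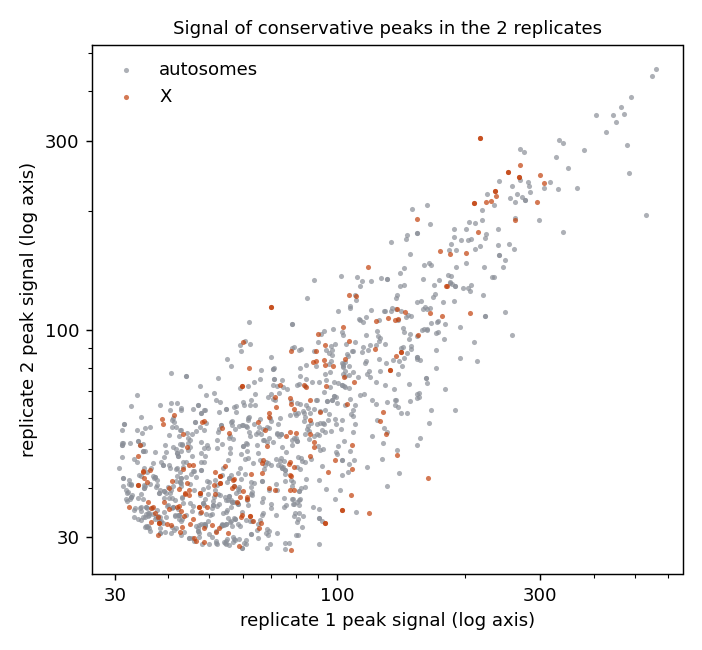
Signal value of each conservative peak in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the peak caller's units, with peaks on X and on the autosomes in different colours. The 1152 peaks with a value in both replicates lie along a rising band (r = 0.82 on the log2 scale), and the spread is widest among the weaker peaks.

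The highest signal in the conservative list, 1010, belonged to a peak at III 10759109 to 10759407, whose summit was intergenic and 54 bp upstream of tasp-1 (WBGene00010480), with a signal of 559.9 in replicate 1 and 455.6 in replicate 2. Next came a peak at III 3867445 to 3867728, 284 bp upstream of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit, with a signal of 987 (547.9 and 436.8 in the replicates). The peak 262 bp upstream of mog-4 (II 14561716 to 14561984), a gene of pre-mRNA splicing and germline sex determination, had a signal of 868. At IV 4749942 to 4750208 a signal of 818 lay in the shared upstream region of Y17G9B.5 and rpl-20. Further peaks among the strongest 25 lay upstream of rpl-15 (779), of cdc-48.1, which encodes an AAA ATPase that extracts ubiquitinated proteins (769), of tos-1, a gene known as a splicing reporter (762), of hsr-9 and rps-19 from a single peak (743), of cox-5B, a subunit of cytochrome c oxidase (741), and of rpl-35 (647). Signals of these 25 peaks ranged from 537 to 1010. Of the 25, 19 had their summit in a promoter window. The 2 on X had summits 289 bp upstream of puf-9 (545) and 4003 bp downstream of the start of W02H3.3 (537), in intergenic sequence for the latter.

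A pair of peaks near K08F11.1 on IV had signals of 813 and 735 with summits 2886 bp and 452 bp downstream of its start. The summit of a peak with signal 785 was 787 bp upstream of F59C6.18 and within 250 bp of the small nucleolar RNA gene F59C6.15. A peak of 645 beside ZK1248.17 and a peak of 563 beside egg-5 lay within 250 bp of sls-2.1 and sls-2.4, genes of the SL2 spliced leader RNA. F58D12.3 (626) and K07D4.2 (602) had summits 2658 bp and 2589 bp upstream. Also among the 25 were peaks at tag-340 (596), F40E3.3 (587), ints-4 (555, in the 5' UTR), the histone gene his-37 (549), eif-3.C (547) and Y22D7AL.10, which shares its upstream region with the mitochondrial chaperonin gene hsp-60 (544).

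Most binding was next to protein-coding transcript starts. Of the 1171 conservative summits, 711 (60.7%, interval 57.9 to 63.5) lay between 1000 bp upstream and 200 bp downstream of a protein-coding start, against 25.9% (SD 1.28) of shuffled summits (permutation p = 1e-04, one-sided, the smallest possible). Of 120271 ranked regions that touched no peak of any thresholded list, 25.08% lay in the same windows (Fisher's exact test, odds ratio 4.62, p = 1.43e-144). The share was 62.6% in replicate 1's own list and 64.8% in replicate 2's. The median distance from a conservative summit to the nearest protein-coding start was 422 bp, against 1322 bp for the regions below the threshold. By annotation, 62.2% of summits were intergenic, 21.8% intronic, 3.76% in 5' UTRs, 2.56% in coding exons and 1.71% in 3' UTRs. Coding exons held 24.8% of the regions below the threshold.

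Promoter peaks were also stronger in the list as a whole, though not on X. Their median signal was 124.5 against 102 at the other 460 peaks, a difference of 0.29 on the log2 scale (permutation test with 100000 resamples, two-sided, p = 2e-05, the smallest possible). This test describes the peaks of a single list. On the autosomes the medians were 127 at 628 promoter peaks and 97.4 at 334 other peaks. On X they were 114.2 at 83 promoter peaks and 114.2 at 126 other peaks. Neither part was tested alone.

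Peaks on X were less often at promoters than peaks on the autosomes. On X, 83 of 209 summits (39.7%, interval 33 to 46.7) lay in promoter windows, against 628 of 962 (65.3%, interval 62.2 to 68.3) on the autosomes (Fisher's exact test, odds ratio 0.35, p = 1.69e-11). This comparison was chosen after the peaks were seen. Promoter windows cover 21.8% of X and 27.2% of the autosomes, and among regions below the threshold the shares were 21.3% and 25.9%. The difference was present in each replicate alone, with 36.6% on X against 70.1% on the autosomes in replicate 2 and 41% against 67.4% in replicate 1.

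Binding was spread unevenly over the chromosomes. Chromosomes I and III held more peaks than their length predicts, with 219 peaks on I (1.24 times, exact adjusted p = 0.00135) and 203 on III (1.26 times, adjusted p = 0.00135). Chromosome V held 168, or 0.688 times the expected number (exact adjusted p = 7.26e-08), and IV held 175 (0.857 times, adjusted p = 0.0347). II, with 197 peaks, and X, with 209, did not pass the test (exact adjusted p = 0.159 and 0.878). These are exact binomial tests, two-sided, with Benjamini-Hochberg adjustment over the 6 chromosomes. The lower count on IV no longer passed in either replicate alone, against the number of genes or against regions below the threshold. Against the number of protein-coding genes, X held more peaks than expected (1.31 times, exact adjusted p = 9.26e-05).

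**Figure D2:**
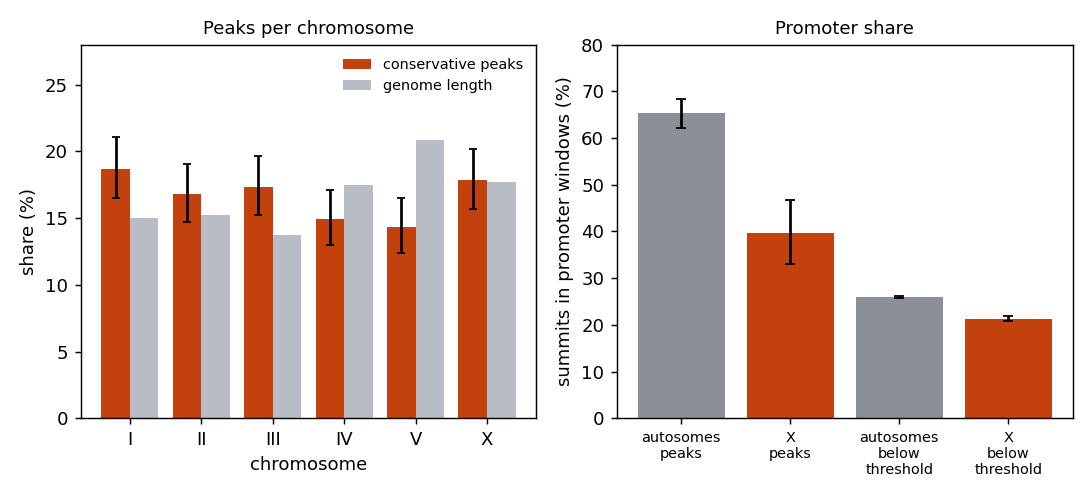
Left, share of the conservative peaks on each chromosome (%) beside the share of the genome length, with exact 95% intervals on the peaks. Right, share of summits in promoter windows (%) on the autosomes and on X, for conservative peaks and for regions below the threshold, with the same intervals; the peaks reach 65.3% on the autosomes and 39.7% on X.

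Genes for small structural RNAs were bound far above their share of the genome. Of the 1171 summits, 60 (5.12%) lay within 250 bp of a tRNA gene, 15.7 times the mean of the shuffles, 55 (4.7%) near a small nucleolar RNA gene, 20.9 times, and 20 (1.71%) near a small nuclear RNA gene, 23.3 times. Each had a permutation adjusted p = 0.00025 from 10000 one-sided shuffles, with Benjamini-Hochberg adjustment over 10 classes. In replicate 2 alone the ratio for small nuclear RNA genes was 35.5, and in replicate 1 alone it was 20.8. The ratios fell to 9.04 (tRNA), 13.3 (small nucleolar RNA) and 14.2 (small nuclear RNA) within 500 bp and rose to 28.9, 31.5 and 41.8 within 100 bp. The conservative peaks covered 67 of 612 tRNA genes, 53 of 346 small nucleolar RNA genes and 20 small nuclear RNA genes. The broad annotated class ncRNA was near 206 summits (17.6%, 4.39 times, permutation adjusted p = 0.00025). Long intergenic RNA genes (10 summits, permutation adjusted p = 0.0154) and microRNA genes (5 summits, adjusted p = 0.047) also passed, and antisense RNA genes (4 summits, adjusted p = 0.125) did not. Antisense RNA genes passed in replicate 1 alone (3.15 times, permutation adjusted p = 0.035) and within 500 bp (permutation adjusted p = 0.0399). The ratio for microRNA genes was 2.98 in the conservative list, 5.02 in replicate 2 alone and 6.76 in replicate 1 alone. The long intergenic class did not pass in the other list of the whole series, in replicate 2 alone or within 100 bp, and the microRNA class did not pass within 100 bp or with only the strongest summit within 500 bp. Genes of piRNAs and pseudogenes were near 1.02% and 1.62% of summits, below the shuffled means of 3.21% and 3.87%, which the one-sided test does not assess. No summit lay near an rRNA gene, which allows a share of up to 0.315% (exact 95% limit). The shuffled mean for this class was only 0.0184%, so the count of 0 does not show that binding is absent.

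**Figure D3:**
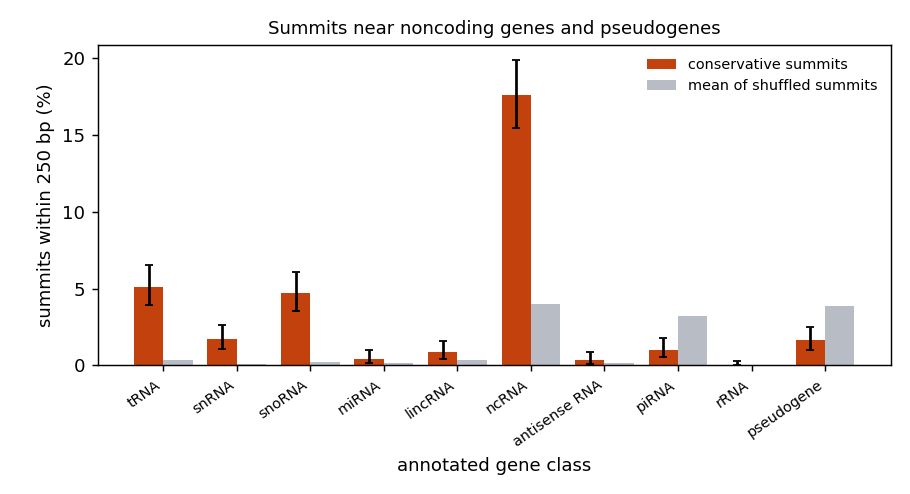
Share of conservative summits within 250 bp of a gene of each annotated class (%), with exact 95% intervals, beside the mean share of shuffled summits. The bars for tRNA (5.12%), small nucleolar RNA (4.7%) and ncRNA (17.6%) genes stand above their shuffled means, and those for piRNA genes and pseudogenes stand below.

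Ribosomal protein genes were the most frequently bound of the 30 gene lists fixed in advance. A summit lay in the promoter window of 945 of the 19973 protein-coding genes, or 4.73%. Among ribosomal protein genes it was 46 of 82 (56.1%, interval 44.7 to 67), with an odds ratio of 27 (Fisher's adjusted p = 5.31e-38), and these included 26 of 47 genes of the large subunit and 19 of 31 of the small subunit. The strongest were rpl-3 (987), rpl-20 (818), rpl-15 (779) and rps-19 (743). The median signal was 168 at the bound ribosomal protein genes and 132 at the other 899 bound genes. With the nearest gene only, 27 of 82 ribosomal protein genes were bound (32.9%, odds ratio 14.7). Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 30 lists was used throughout.

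The lists of mitochondrial respiration, of proteasome and heat shock genes and of translation factors and tRNA synthetases were also bound more often than other protein-coding genes. No sample without the tagged protein was analysed, so recovery by any immunoprecipitation cannot be told apart from CEH-88 binding at these genes. Of the genes of mitochondrial respiration, 12 of 46 were bound (26.1%, odds ratio 7.19, Fisher's adjusted p = 7.72e-06), led by cox-5B (741), cox-5A (515), atp-1 (341) and cox-6B (241). Of the proteasome and heat shock list, 19 of 93 were bound (20.4%, odds ratio 5.26, Fisher's adjusted p = 5.8e-07). With the nearest gene only it was 9 of 93 (odds ratio 3.11). Its strongest members were the chaperone genes hsp-60 (544), hsp-1 (508), cct-8 (453) and hsp-90 (432). Translation factors and tRNA synthetases followed with 12 of 70 (17.1%, odds ratio 4.21, Fisher's adjusted p = 0.000494), led by eif-3.C (547), eef-1A.1 (297), eif-3.B (270) and eef-1G (225).

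Chemosensory, immune, detoxification and ion channel genes were bound less often. Only 4 of 1310 chemosensory receptor genes were bound (0.305%, odds ratio 0.0577, Fisher's adjusted p = 7.74e-22), namely sri-5 (307), srh-16 (176), srh-2 (169) and srw-85 (68.2). Of the C-type lectin and innate immunity list, 2 of 348 were bound, clec-126 and clec-87 (odds ratio 0.115, Fisher's adjusted p = 9.95e-05). Of the detoxification list, 1 of 215 was bound, gst-27 (odds ratio 0.0931, Fisher's adjusted p = 0.0024), and of the ion channels 1 of 151, the innexin gene inx-7 (odds ratio 0.133, adjusted p = 0.0408). Without 1 replicate the odds ratios ranged from 0 to 0.175 for the lectin and immunity list and from 0 to 0.208 for ion channels. The ion channel call did not pass in replicate 2 alone, with windows of 500 bp or with the nearest gene only, and the detoxification call did not pass in replicate 2 alone (odds ratio 0.145, Fisher's adjusted p = 0.0691).

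The remaining 22 lists did not pass the test. Among homeobox genes, the family of CEH-88 itself, 2 of 100 were bound, ceh-38 (signal 218, in its 5' UTR) and ceh-5 (111.8), with an adjusted p of 0.481. The cell cycle list had 6 of 47 bound (Fisher's adjusted p = 0.0618), with pcn-1 (358) and the retinoblastoma homologue lin-35 (309) the strongest, and the histone list had 7 of 81 (adjusted p = 0.244), with his-37 (549) and his-67 (331). In the other list of the whole series the histone list passed Fisher's exact test (odds ratio 3.48, adjusted p = 0.00109), as the cell cycle list did at a score of 1000 (adjusted p = 0.0364). Neuropeptide genes had 1 of 145 (ins-39, 311, Fisher's adjusted p = 0.0535) and nuclear hormone receptors 5 of 274 (adjusted p = 0.0615), with nhr-47 (181) and nhr-48 (106). The neuropeptide list passed Fisher's exact test as less often bound in the other list of the whole series (adjusted p = 0.0226), in replicate 1 alone (0.0429), with windows of 500 bp (0.0266) and 2000 bp (0.0104) and among genes with a ranked region (0.025). Nuclear hormone receptors did so in replicate 1 alone (odds ratio 0.224, Fisher's adjusted p = 0.00625) and with 2000 bp (0.0123). Germline genes had 3 of 40 (Fisher's adjusted p = 0.524), with ifet-1 (382) and cgh-1 (107), and pan-neuronal genes 3 of 28 (adjusted p = 0.284), with nsf-1 (166) and ric-19 (144). In replicate 1 alone the pan-neuronal list passed Fisher's exact test (odds ratio 6.86, adjusted p = 0.001). The heterochronic and dauer list had 3 of 34 (Fisher's adjusted p = 0.36), with lin-46 (183) and lin-28 (118), and passed with 2000 bp (adjusted p = 0.0427). Collagens had 4 of 176 (Fisher's adjusted p = 0.284; col-38 and col-63), bHLH factors 2 of 41 (adjusted p = 0.813; hlh-11 and mdl-1), the signalling list 3 of 62 (adjusted p = 0.824; wrm-1 and egl-17), body wall muscle 1 of 50 (adjusted p = 0.813; cpn-3) and the microRNA list, which matched 7 annotated symbols, 1 (adjusted p = 0.432; mir-353). No gene was bound in 9 lists, those of intestine (0 of 31), pharynx (0 of 31), epidermis and seam (0 of 47), glia (0 of 29), ciliated sensory neurons (0 of 55), neuron fate and axon guidance (0 of 43), neurotransmitter synthesis (0 of 20), neuropeptide processing (0 of 11) and hedgehog-related genes (0 of 85, Fisher's adjusted p = 0.0876). The hedgehog-related list passed among genes with a ranked region (Fisher's adjusted p = 0.0436). Several of these zeros changed with the setting. Epidermis and seam, glia and neuropeptide processing had 1 target each in the other list of the whole series. Neuron fate and axon guidance had 1 in replicate 1 alone. With 2000 bp, the hedgehog-related and ciliated sensory neuron lists had 2 each. With 31 genes, a count of 0 allows a share of up to 11.2% (exact 95% limit).

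**Figure D4:**
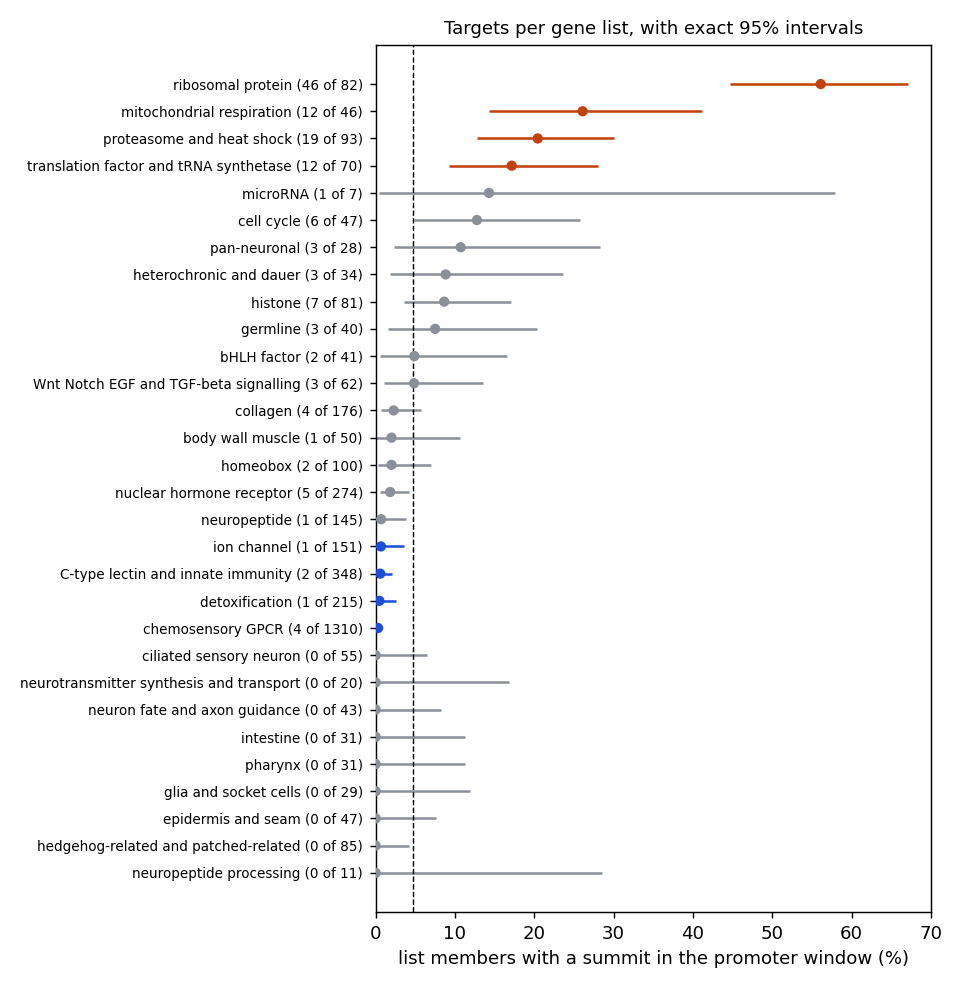
Share of each list's members with a summit in the promoter window (%), with exact 95% intervals and counts beside the names; the dashed line marks all protein-coding genes (4.73%). Colours mark lists past the adjusted p of 0.05 with more or fewer bound members, and ribosomal protein genes stand highest at 56.1%.

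Summits were rich in G and C, and the homeodomain core TAATTA was not raised in the planned comparison. Windows of 50 bp on each side of the summits had 46% G and C, against 36.1% in windows 250 bp away. Of 2080 hexamers, 518 were more frequent and 383 less frequent at summits (exact binomial test, two-sided, Benjamini-Hochberg adjustment). The leading hexamers were ACGCGC (13% of summit windows, 1.28% of flanks), GACGCA (15.1% and 2.52%) and ACGCAG (15.3% and 2.9%). Among the 12 hexamers fixed in advance, GAGAGA (19.6% and 7.22%, exact adjusted p = 9.76e-21) and the E-box CACGTG (6.06% and 1.54%, adjusted p = 8.77e-11) were more frequent, as were CAGCTG (adjusted p = 0.0199), AAGGTC (adjusted p = 0.0162) and TGACAG (adjusted p = 0.0283). TAATTA was in 2.56% of summit windows and 5.34% of flanks (ratio 0.48, exact adjusted p = 0.00075), TAATTG in 4.01% and 8.33%, TGATAA in 4.7% and 9.44%, and TATAAA in 6.66% and 11.3%. TAATCC (exact adjusted p = 0.269), TGACGT (0.117) and GTAAAC (0.592) did not pass. These calls varied with the setting. AAGGTC did not pass in either replicate alone, in the other list of the whole series, at a score of 1000, with flanks 500 bp away or against regions below the threshold of the same promoter class. TGACAG did not pass in either replicate alone, with windows of 100 bp on each side, with flanks 500 bp away or against those regions. TAATTA did not pass in replicate 2 alone (ratio 0.65, exact adjusted p = 0.18). TAATCC passed as less frequent with windows of 100 bp on each side (exact adjusted p = 0.028) and with flanks 500 bp away (0.0423). TGACGT passed as more frequent in replicate 1 alone (exact adjusted p = 0.00327) and against regions below the threshold of the same promoter class (ratio 1.71, adjusted p = 0.00887).

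Matching the background on base composition changed several of these values. Against regions below the threshold with the same promoter class, 549 hexamers were more frequent and 423 less frequent. With the same G and C content as well, a background chosen after the data were seen, 257 were more frequent and 335 less frequent. There TAATTA had a ratio of 1.62 (exact adjusted p = 0.136) and TATAAA a ratio of 1.3 (adjusted p = 0.193), where matching on promoter class alone gave 0.51 and 0.58, and TAATTG, TGATAA, CAGCTG and TGACGT, which passed with promoter class alone, did not pass. CACGTG (ratio 2.22, exact adjusted p = 8.94e-05) and GAGAGA (ratio 2.46, adjusted p = 2.41e-17) stayed more frequent, and ACGCAG led the list (15.3% and 3.68%). AAGGTC and TGACAG passed with neither of these backgrounds. TAATCC passed as less frequent with the content matched (ratio 0.53, exact adjusted p = 0.0284) and not with promoter class alone (0.0761).

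The genes carried by the transgene had no peak. The endogenous ceh-88 (WBGene00008195, IV 17329188 to 17332435, plus strand) and unc-119 (WBGene00006843, III 10902641 to 10908935, plus strand) lay more than 10 kb from every peak of the 4 thresholded lists. The strongest ranked region within 10 kb of ceh-88 in the list from both replicates had a signal of 58.2 and had rank 1926 of 122189, and the strongest near unc-119 had a signal of 36.4. No ranked region of any list lay inside ceh-88. Replicate 1 listed 6 weak ranked regions inside unc-119 and replicate 2 listed 0.

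Peaks found in a single replicate were weaker, and their promoter share was lower in both replicates. With touching peaks counted as shared, the difference in promoter share passed the test in replicate 1 only, which had more unshared peaks. The 582 peaks found in replicate 1 alone had a median signal of 58.1, against 108.5 at its 546 shared peaks, and 59.3% of them were in promoter windows against 66.1% (Fisher's exact test, odds ratio of shared against unshared 1.34, p = 0.0193). In replicate 2 the 150 unshared peaks had a median signal of 52.4 against 81.5, and promoter shares were 58.7% and 66.4% (odds ratio 1.39, Fisher's p = 0.083). With summits within 100 bp as the criterion, the difference in replicate 2 passed as well (odds ratio 1.62, Fisher's p = 0.00591). Most unshared peaks were listed below the threshold by the other replicate: 502 of 582 (86.3%) and 138 of 150 (92%) overlapped one of its ranked regions. The ranked lists are long, and the same regions placed at random within chromosomes did so in 53.5% and 47.3% of cases on average (permutation p = 1e-04 in both directions, one-sided, a comparison chosen after the data were seen). The 3 strongest peaks of replicate 1 alone were nearest to the nuclear hormone receptor gene nhr-49 (178), to C30E1.4 (163) and to hat-1 (154), and those of replicate 2 alone to pdi-6 (102.7), F54F12.1 (100) and epg-8 (99.2).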

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

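The comparison in this part was chosen after the lists were seen. Regions that the authors ranked but left out of their thresholded lists drew attention here: a few regions that reached the authors' score threshold are missing from the thresholded lists. In the ranked list of both replicates, 1181 regions scored at least 830, and 10 of them were absent from the 1171 conservative peaks. They include the region with the highest signal of that list, X 15810998 to 15811185, which has no annotated gene within 500 bp and lies 6935 bp from the nearest protein-coding start, that of Y7A5A.7. A region at the same place was also first by signal in each replicate's ranked list, with 569.1 in replicate 1 and 654.1 in replicate 2, and absent from that replicate's thresholded list. The next by signal among the 10 lay at II 2570511 to 2570906 beside usp-39 (207), at IV 13549296 to 13549691 (192) and at I 4535875 to 4536270 (151). Another, at IV 10176861 to 10177256, lay beside rack-1 and the small nucleolar RNA gene K04D7.17 (70.9). The records of the files name 1 more input for the thresholded lists than for the ranked lists, without saying what it is. Which step left these regions out is not given in the sources used here, and no explanation was tested.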

How the results depend on the processing

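The score of 1000, the strongest summit within 500 bp, the ranked-region null, the background of equal G and C content and every test of X against the autosomes were chosen after seeing the data. Promoter share, signal at promoters and the X contrast kept their direction and passed under each alternative run. The alternatives for signal at promoters did not split it by chromosome. Calls numbered 3 to 4 for chromosomes, 4 to 7 for noncoding classes and 6 to 11 for gene lists. A score of at least 830 removed no peak, so it tests nothing. The overlap of replicate 1 with replicate 2 was 41% with at least 50% of both regions shared and 44.9% with summits within 100 bp, and the converse was 65.9%, 72.6% and, at a score of 1000, 83%. The correlation of signal was 0.31 over all ranked regions with a signal in both replicates, and 0.90 in the conservative peaks without the log. Against regions below the threshold of the same promoter class 549 hexamers were more frequent, and 257 with equal G and C content as well, in place of 518 against the flanks. With both matched, TAATTA (1.62), TATAAA (1.3) and TGACAG (0.886), which had all passed against the flanks, turned, and TGACAG had not passed with promoter class alone (1.08). The unshared peaks of replicate 2 passed with summits within 100 bp (1.62). TGACAG also turned in replicate 2 alone, and the remaining turns were in values that passed neither way. For X they were ratios of 0.977 with the strongest summit within 500 bp, 0.984 against regions below the threshold and 0.908 to 1.03 without 1 replicate, and for II 0.974 against gene number. For GTAAAC they were 0.912 at a score of 1000 and 0.935 with 100 bp each side. Odds ratios turned for neuropeptide processing (1.8 in the other list of the whole series, 1.54 with 2000 bp), for the signalling list (0.917, 0.783 and 0.417 in that list and with 2000 and 500 bp), for germline (0.653) and heterochronic genes (0.772) with 500 bp, and for microRNA (0 with 500 bp or the nearest gene). Without 1 replicate the ranges were 0 to 1.04 for signalling, 0 to 3.38 for microRNA, 0.784 to 2.22 for bHLH factors, 0.804 to 1.66 for germline genes and 0.914 to 1.37 for TGACAG. The cause of these changes was not tested. The unknown read depth limits how far a missing peak can be read.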

Other observations

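The tests of sequence on X, of tRNA genes on X, of repeated sequence in autosomal peaks and of the longer motif in this part were chosen after the result was seen. Among the spliced leader genes, a conservative summit lay within 250 bp of 9 of 18 sls-2 genes (SL2), and of 0 of 12 sls-1 genes (SL1), with 7 and 8 sls-2 genes in replicates 1 and 2. The difference between the families was not tested. Repeated sequence was measured only in summit windows, so whether a peak could have been called at the sls-1 genes is not known. The count of 0 is therefore no evidence that binding is particular to sls-2 genes. The strongest were at sls-2.1 (signal 645), sls-2.4 (563) and sls-2.2 (509), the last with 61.1% of its 30-mers repeated elsewhere. Binding at tRNA genes was more frequent on X, with 42 of 276 genes (15.2%, exact 95% interval 11.2 to 20) against 25 of 336 (7.44%, interval 4.87 to 10.8) on the autosomes (Fisher's exact test, odds ratio 2.23, p = 0.00263). The 42 genes came from 37 peaks and the 25 from 23 peaks. Genes that share a peak are not independent, which the test and intervals do not take into account. The strongest peak at a tRNA gene had its summit at X 8036437, between the tRNA gene WBGene00022939 and xol-1 (signal 536). That tRNA gene lies at 8036685 to 8036757, so the summit is close to the limit of 250 bp. Of the 60 summits near tRNA genes, 56 lay within 100 bp. The same peak is also among the 16 X peaks with the 8-mer CCCTGCGC described below, so it is no clear case of binding at a tRNA gene. Leaving out peaks at tRNA genes moved the odds ratio of promoter location on X against the autosomes from 0.35 to 0.415 (Fisher's exact test, p = 1.99e-07).

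Weak summits stood beside strong ones. Of the conservative peaks, 31 had a signal under 17.2, the median of the ranked list, and 30 of these lay within 500 bp of a stronger conservative peak, at a median distance of 208 bp over the 31. Keeping the strongest summit within 500 bp left 1095 peaks.

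The 8-mer CCCTGCGC lay within 50 bp of 16 of 209 X summits and 0 of 962 autosomal summits (Fisher's exact test, p = 6.52e-13, adjusted p = 1.29e-09 over 1976 8-mers), with a median signal of 372 against 115.1 for all peaks, and in 12 X peaks and 1 of 923 autosomal peaks of replicate 1 and 11 X peaks and 0 of 586 autosomal peaks of replicate 2. Reads shared between exact copies of these windows are an unlikely source, since the median share of repeated 30-mers in them was 0%. Diverged copies were not measured. A mere excess of the 8-mer on X falls short as well. It has 81 occurrences on X and 233 on the autosomes (4.57 and 2.82 per Mb), counts that played no part in its choice, and 22 and 5 of them, the 5 all on III, lay within 200 bp of a summit (odds ratio 17). The 8-mer was picked from the same summits, so this ratio is no independent measure of their preference for X. Among the 16 X peaks, those at X 2996931 to 2997222 and X 2997145 to 2997374 overlap. Fisher's exact test counted them as separate summits. Sites recovered by any immunoprecipitation stay open and cannot be told apart from CEH-88 binding, because 0 samples without the tagged protein were analysed, and no biological explanation was decided by a test.

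The reverse complement GCGCAGGG is, from background knowledge, the core of a motif at elements that recruit the dosage compensation complex to X. Whether recruitment elements of the dosage compensation complex are among these sites stays open. Of 10 X occurrences inside the longer GCGCAGGGAG, 7 lay within 200 bp of a summit, against 15 of the other 71 (odds ratio 8.71). This decides nothing, because the 8-mers inside the longer motif, CCCTGCGC, CGCAGGGA and CTCCCTGC on either strand, were all found by searching the same X summits, and no map of that complex was used here.

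Peaks at small RNA and ribosomal protein genes could come from reads shared between repeated copies. At ribosomal protein genes and small nucleolar RNA genes the median share of repeated 30-mers in the summit windows was 0% (44 and 55 peaks), which argues against it. At tRNA genes the median was 10.4% (bootstrap 95% interval 1.39 to 29.2, 60 peaks) and at small nuclear RNA genes 5.56% (0 to 35.4, 20 peaks), and these intervals leave it open. For all 4 classes, sites recovered by any immunoprecipitation cannot be told apart from CEH-88 binding with 0 samples without the tagged protein. The same limit holds for the other gene lists and for promoter peaks.

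Some autosomal peaks away from promoters may reflect copies of repeated sequence. At least 50% of the 30-mers were repeated in 47 of 334 such windows (14.1%) and in 41 of 628 windows inside promoters (6.53%), an odds ratio of 2.34 (Fisher's exact test, p = 0.00023). The remaining windows of the 334 were below that share. Exact 30-mers miss diverged copies and sequence outside the window, so this sets no upper limit on peaks that come from repeats. Autosomal sequence outside peaks was not compared, so the excess away from promoters may not be particular to peaks.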
